A study of Halobacterium salinarum NRC-1 with 56 samples.

How the data were processed

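The data are 2-colour arrays of total RNA from 1 turbidostat culture of Halobacterium salinarum NRC-1 at 28 time points, 2 arrays each. The culture RNA was labelled for 532 nm (channel 1) on 1 array and for 647 nm (channel 2) on the other, against a common reference RNA. The deposited values are the authors' log ratio of the channels, 1 value per spot. Labels conflict for some arrays: the pair at 0 minutes has unlike titles, the swap at 367 minutes is titled as high oxygen, the swap at 382 minutes is described as 362, and 1 array at 432 minutes has a protocol of 55 minutes. The minutes of the titles were used, except at 0 minutes, where both descriptions say at the shift. The log base, direction, centring and earlier processing are not given in the sources used here, and scanner intensities were not used here, so signal over background is unknown. A log2 scale had been assumed before the data were examined; the text keeps the deposited log-ratio units, and a fold is given only as what it would be under base 2 or base 10. Values ran from −1.60 to 1.62. Array medians ran from 0.0599 to 0.295 with culture RNA in channel 1 and from −0.155 to 0.0267 with it in channel 2, and no centring was applied in the results reported first.

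Exact zeros, 0.627% of all values, were treated as missing. They left 144 features without a value at 770 minutes and 1 at 750 minutes. At 770 minutes they made up 10.0% of the channel-1 array and 19.3% of the channel-2 array. The spots at 0 there had mean absolute ratios of 0.282 and 0.319 on the other arrays, beside 0.172 and 0.151 for the remaining spots. Values lost at 770 minutes were therefore more often those of features with strong ratios. The 4 spots of a feature were averaged, with a median r across probes between arrays of 1 orientation of 0.851 in channel 1 and 0.640 in channel 2. Which spots belong to a feature was read from the 133 named genes, each with 4 spots at fixed offsets, and extended to the unnamed spots (correlation between adjacent spots of a feature 0.991, between its 2 places on the array 0.939). The print layout of 48 blocks of 14 lines by 16 spots was found from the data. Symbols come from a probe table for the platform; all 133 were found in a reference annotation of another strain of the species (assembly of strain 91-R6), which was used for names only, and 0 of the probe table's Entrez numbers matched it. No locus tags or coordinates are given for that reason. The other 2555 features were tested without names.

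A feature's value at a time point is the mean of both orientations. The rule fixed before the data were examined gave channel-2 arrays the opposite sign wherever the 2 arrays of a time point correlated negatively across probes, as they did at 26 of 28 time points. It was not followed. Means over time correlated at −0.733 across features between the orientations, whereas the deviations from those means correlated positively at 27 of 28 time points (lowest −0.134 at 760 minutes, highest 0.812), and at 26 of 28 with the profile shared by all features at different strengths removed (median 0.337; highest median of 200 shuffles 0.181). All 2460 exact zeros of channel-2 arrays are written as −0 and none of the 1316 of channel-1 arrays. The mean as deposited had an SD over time of 0.0715 and 12.1% of its variance between print blocks; with channel 2 turned these were 0.0424 and 26.3%. If channel-2 values carry the other sign, a dye effect that drifts over time would also make the deviations correlate positively. The correlations therefore do not settle the sign. This choice was made after results and time courses of named genes had been seen, and no gene's known biology served as its basis. If the sign as deposited is right, spots hold a constant part that depends on the dye. Differences between time points cancel it as far as it stays constant. With channel 2 turned, the same part would be the ratio of culture to reference RNA. The correlation of the ratio with that dye part went from 0.895 at 0 minutes to 0.250 at 180 minutes. The ratio comes from the sum and the dye part from the difference of the 2 arrays. Their correlation therefore depends on how unequal the SDs of the arrays are, and does not by itself show a change of the dye effect. The SD of the channel-1 array went from 0.342 at 0 minutes to 0.138 at 780 minutes, and that of the channel-2 array from 0.0849 to 0.121.

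Comparisons used limma 3.58.1 with statmod 1.5.0 in R 4.3.3 (lmFit and eBayes, 2-sided moderated tests, Benjamini-Hochberg adjustment over all features, threshold 0.05). 3 contrasts came from 1 fit of 6 groups over 28 time points: the first high-oxygen phase against the low-oxygen phase, the shift to low oxygen against the first high-oxygen phase, and the second shift to high oxygen against the low-oxygen phase. The time points 1 minute before and at the first shift are groups of 1 and add no estimate of spread. The second and the first shift to high oxygen were compared over 10 time points with the minutes since the shift as a block. Trends were slopes on log2 of the minutes since the shift plus 5, over 9 time points in high oxygen and 13 in low oxygen. A feature was tested where at least 50% of the time points of each group had a value. The ± values are limma's SE for differences and slopes and the SD over time points for means.

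Gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Of the 21 lists fixed before the data were examined, 8 had no measured gene, 8 had 1 or 2 genes and are described only, and 5 were tested. A further 10 were written after the gene names and before the values had been seen, and these were tested too. In the results reported first, however, the histidine degradation list was tested for the trends only. Lists of at least 3 genes with values at all time points of a fit were tested, adjusted over the 14 or 15 lists of that fit. The genes named were, per comparison of groups, the 8 highest and 8 lowest differences among named genes past the threshold, per trend the 5 steepest each way, and from each list the member with the smallest adjusted p and the one with the largest change in the first contrast listed; other genes named as members of lists, neighbours or features that stand apart were chosen after their values had been seen. The fits were tested on simulated data with the deposited spread and 200 of 2688 features changed. Of changes of 0.1, between 28.4% and 73.3% were recovered, and of changes of 0.2, between 90.9% and 97.0%. For trends of 0.04 the shares were 73.7% and 83.2%, and 3.41% to 10.0% of calls were false. The simulated time points were drawn independently, without serial correlation, dye drift, array scaling or position effects. These shares therefore test the fitting and are not error rates of the deposited data.

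Alternatives fixed before the data were examined were median centring of arrays, quantile normalization, either orientation alone, both arrays entered with the time point as a random block, the median over a feature's spots, leaving out the fifth of features whose orientations disagree most, an adjusted p of 0.01, time points whitened for serial correlation, leaving out each time point, fitting only the groups compared, time points from 45 minutes on, oxygen state with elapsed minutes as a covariate, no block, and ranks of time points. Added after the data had been seen were zeros kept as values, a loess of each time point on the mean profile (span 0.5), values relative to neighbouring spots of the print block (7 lines by 14 spots) with and without centring, leaving out 755 and 770 minutes, turning the sign of channel-2 arrays, and leaving out the 380 unnamed features of the last 2 lines of print blocks. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.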

Results

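RNA of the halophilic archaeon Halobacterium salinarum NRC-1 was measured at 28 time points while the oxygen supply of 1 culture was raised, lowered and raised again. The culture stood in a turbidostat, a vessel in which fresh medium holds the cell density steady. Per the labels, medium flowed in high oxygen and did not flow in low oxygen, so oxygen and flow changed together. 1 time point came 1 minute before the first shift to high oxygen and 1 at the shift itself. The first high-oxygen phase followed with 8 time points from 5 to 360 minutes. The shift to low oxygen was sampled at 4 time points from 362 to 382 minutes, and the low-oxygen phase after it at 9 time points from 387 to 747 minutes. The second shift to high oxygen gave 5 time points from 750 to 780 minutes. At each time point the same RNA was set against a common reference RNA on 2 arrays with the dyes exchanged, 56 arrays in all, so 1 time point is 1 replicate and its value is the mean of both arrays. Because the time points come from 1 culture, p-values measure scatter over time within that culture and not between cultures. Slide, print and hybridization batches are not given in the sources used here, so a batch that follows time cannot be told from a trend over time. The number of arrays limits the precision.

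Every array held 10752 spots, 4 for each of 2688 features. A gene symbol was available for 133 features; the names of the other 2555 were not given in the sources used here. Of the 21 gene groups fixed before the data were examined, 8 had no named gene on the array: DMSO and TMAO respiration, gas vesicles, terminal oxidases and halocyanins, ATP synthase, RNA polymerase, general transcription factors, iron uptake and regulation, and fatty acid oxidation. The deposited values are log ratios whose base and centring are not given in the sources used here, so all differences are in these log-ratio units. Array medians ran from 0.0599 to 0.295 with the culture RNA in channel 1 and from −0.155 to 0.0267 with it in channel 2.

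A higher value likely means more culture RNA than reference RNA, a direction that rests on the order of the RNAs in the descriptions and on how zeros are written. A rule set before the data were examined would have turned the sign of the channel-2 arrays, because the 2 arrays correlated negatively at 26 of 28 time points (Pearson's r across probes from −0.771 to 0.204; probes are not independent replicates). The sign was kept as deposited instead, a departure decided after results and time courses of named genes had been seen. Its basis is that each feature's deviations from its own mean over time correlated positively between the orientations at 27 of 28 time points (median r across features 0.399; highest median in 200 shuffles of the time points 0.268). Such a correlation would also arise if channel-2 values carry the other sign and the dye effect drifts over time. It therefore does not settle the sign. Counts with the sign turned stand beside each comparison, and rankings are of the values as deposited.

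A set of 380 unnamed features, those in the last 2 of the 14 lines of features in each print block, moved almost as 1. Their median was 0.382 at 0 minutes, 0.0465 at 360 minutes, 0.0840 at 747 minutes and 0.0175 at 780 minutes. Whether they are control spots is not given in the sources used here. Their movement is given beside the genes that moved by a like amount. In the plot of 8 genes over time, hutI lies close to it and sucC does not.

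**Figure D1:**
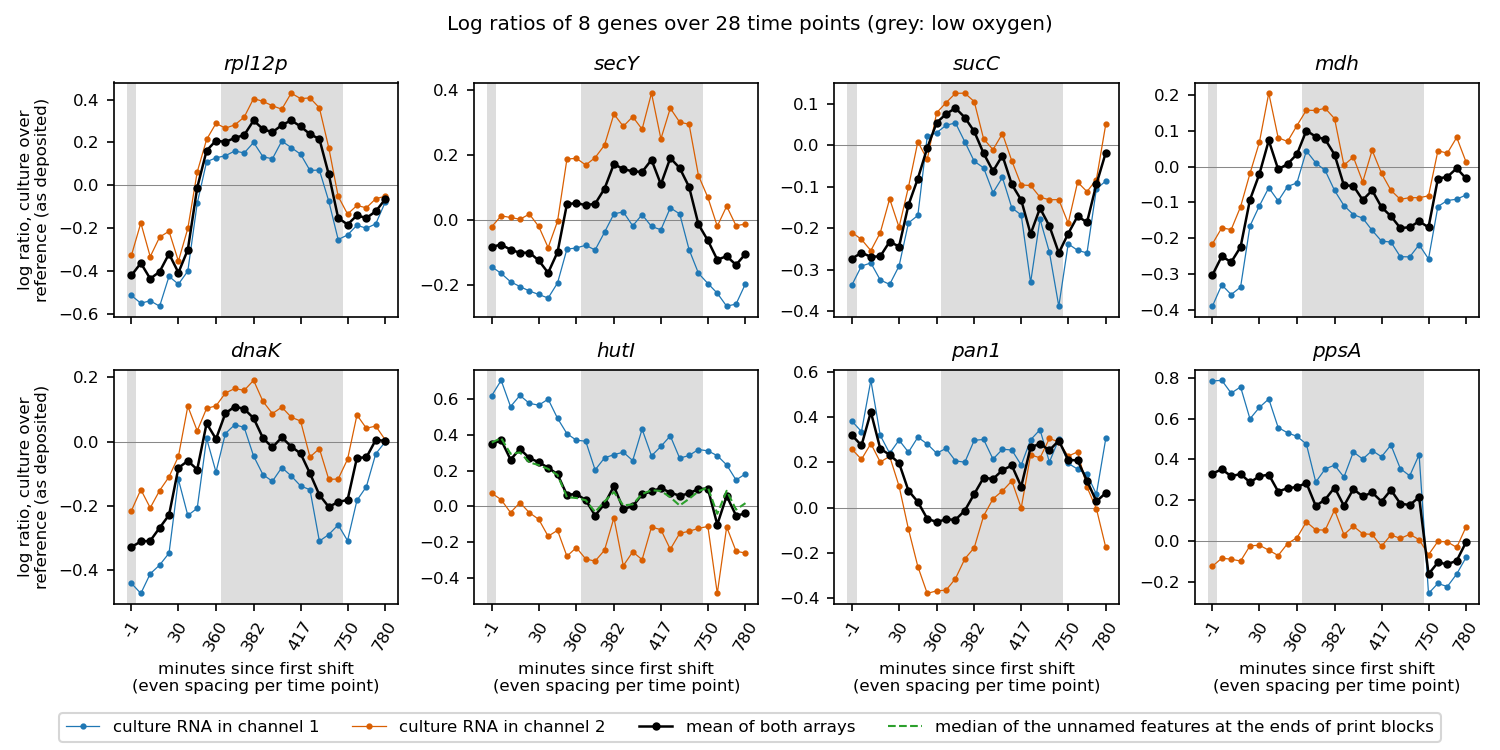
Log ratios of 8 genes (y axis, culture over reference as deposited) at 28 time points (x axis, evenly spaced, minutes since the first shift; grey, low oxygen), with both dye orientations, their mean and, for hutI, the median of the 380 unnamed features. The mean for rpl12p went from −0.364 at 0 minutes to 0.209 at 360 minutes and −0.152 at 747 minutes, and that for ppsA was 0.214 at 747 minutes and −0.163 at 750 minutes.

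Which genes kept changing after oxygen was raised was asked over the 9 time points from 0 to 360 minutes. In the tricarboxylic acid cycle, which oxidises acetyl groups for respiration, sucC and sucD, the subunits of succinyl-CoA synthetase, had slopes of 0.0577 ± 0.00665 and 0.0612 ± 0.00604 (SE, n = 9 time points) per doubling of the minutes since the shift plus 5. The gene sucC was at −0.259 at 0 minutes and at 0.0538 at 360 minutes. Steepest of all named genes was rpl12p, a protein of the ribosome's stalk, with a slope of 0.114 ± 0.0133 (0.0171 with the sign turned, not past the threshold); it stood at −0.301 at 45 minutes and at 0.162 at 180 minutes. The chaperone gene dnaK rose with a slope of 0.0644 ± 0.00733, hemA (glutamyl-tRNA reductase, haem synthesis) with 0.0609 ± 0.00606 and glyA (serine hydroxymethyltransferase) with 0.0596 ± 0.00711. The proteasome-activating nucleotidase gene pan1 fell, with a slope of −0.0757 ± 0.00839, −0.0264 in the channel-1 arrays and −0.125 in the channel-2 arrays.

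In this phase 6 of the 6 measured genes of the tricarboxylic acid cycle rose, and 6 when adjusted over the list alone, with a median slope of 0.0484 against −0.0233 for all features (camera, adjusted p = 2.42e-06; adjusted p = 0.0626 with an estimated correlation and 0.831 with the sign turned). The list also holds mdh (malate dehydrogenase, 0.0553 ± 0.00893), sdhC (succinate dehydrogenase, 0.0414 ± 0.00525), icd (isocitrate dehydrogenase, 0.0248 ± 0.00548) and citZ (citrate synthase, 0.0194 ± 0.00567). Both measured respiratory dehydrogenase genes, nuoL and sdhC, rose. Of the 4 genes listed under proteasome and proteases, the proteasome subunit genes psmA and psmB and panB rose and pan1 fell, with a median of 0.0145 and a mean of −0.00350; panB is named for a coenzyme A synthesis enzyme and not for the proteasome. Relative to neighbouring spots psmA, psmB and panB did not pass, nor did citZ. All 3 histidine degradation genes fell (hutU, hutI and hutG; a list chosen after the gene names were known), with hutU at −0.0617 ± 0.00601. The 380 unnamed features fell alike, with a median slope of −0.0548 (SD 0.0145), and 27 of the 94 named genes that changed lay within 2 SD of it, among them hutU, hutI, hutG, purB, gatC, mamA and pan1. The purine gene purB (slope −0.0635 ± 0.00690), gatC (a subunit of the enzyme that amidates glutamyl-tRNA, −0.0592 ± 0.00788) and mamA (methylaspartate mutase, −0.0587 ± 0.00616) also fell.

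The trend passed an adjusted p of 0.05 in limma for 2051 of 2688 features, 359 rising and 1692 falling, and for 94 of the 133 named genes. Of these genes 90 had the same sign in both orientations, as did 87.7% of all features. The sign was kept because the orientations move alike, so this agreement is no separate evidence for the calls. With arrays centred on their medians 883 rose and 998 fell, with quantile normalization 448 and 466, and after a loess on the mean profile 496 and 566. After that loess hutI had a slope of −0.00184 and hutG of 0.00589, neither past the threshold, while rpl12p was at 0.109 and sucC at 0.0361, both past it; psmA, psmB, panB, nuoL, pan1, gatC and mamA did not pass there. With the sign turned 98 features passed, sucD was at −0.00238 and pan1, past the threshold, at 0.0493; citZ, icd, psmB, nuoL, hutG, hutI and mamA turned their direction too. Along this phase the correlation of the 2 arrays across probes went from 0.0541 at 0 minutes to −0.771 at 180 minutes. That of the ratio with the dye part of the signal, a dye part only if the sign as deposited is right, went from 0.895 to 0.250. The latter depends on how unequal the arrays' SDs over spots are. In channels 1 and 2 these were 0.357 and 0.117 at 0 minutes, and 0.220 and 0.196 at 180 minutes.

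What changed in the first 20 minutes after oxygen was removed was asked with the 4 time points of the shift to low oxygen. They were set against the 8 of the first high-oxygen phase, whose mean takes in its early time points. Single genes, lists and counts of this contrast therefore also hold changes from before oxygen was removed. Among the named genes rpl12p differed most as deposited (0.0132 with the sign turned), higher by 0.429 ± 0.0992 (SE; 0.240 ± 0.0437, SD, n = 4, against −0.189 ± 0.267, n = 8), which would be 1.35-fold if the logs are base 2 and 2.69-fold if base 10. Among metabolic genes sucC rose by 0.215 ± 0.0537, sucD by 0.197 ± 0.0572, hemA by 0.191 ± 0.0492, eno (enolase, glycolysis) by 0.181 and guaB (IMP dehydrogenase, GMP synthesis) by 0.169. The chaperone gene dnaK rose by 0.214 ± 0.0553. These genes had climbed during the high-oxygen phase: sucC was at 0.0538 at its last time point and at 0.0890 at 367 minutes, and rpl12p at 0.209 and 0.221. Lowest were mamA (−0.185 ± 0.0456), hutI (−0.177 ± 0.0422), hutU (−0.154 ± 0.0452) and pan1 (−0.152 ± 0.0641).

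At this shift 5 of 6 genes of the tricarboxylic acid cycle rose, and 5 when adjusted over the list alone (median 0.114 against −0.0613 for all features; camera, adjusted p = 0.000231; adjusted p = 0.220 with an estimated correlation, and 0.0880 after the loess). Of 4 cobalamin genes 3 rose, cbiG (0.151 ± 0.0258), cbiT (0.121 ± 0.0300) and cobN (0.117 ± 0.0235), and 3 when adjusted over the list alone (camera, adjusted p = 0.000599; adjusted p = 0.0381 with an estimated correlation; 0.393 after the loess). The phosphate regulator gene phoU, its list's only measured member, stood at −0.168 ± 0.0202 (n = 4) against −0.315 ± 0.0599 (n = 8) in the high-oxygen phase. Both oxidative stress genes, dpsA (a DNA-protecting ferritin-like protein) and msrA (methionine sulfoxide reductase), were lower (−0.0609 and −0.0639) by about as much as the median of all features, −0.0613; with centred arrays neither passed, and dpsA did not pass relative to neighbouring spots. The gene bat, the bacterio-opsin activator, fell by 0.131. Of the 11 genes listed under flagella and chemotaxis, cheA, cheY and cheB of the signalling core were higher and the receptor genes htr1 and htr7 lower. Relative to neighbouring spots cheA, cheY and cheB did not pass, after the loess they did not pass and cheB was at −0.00736, and with centred arrays htr1 and htr7 did not pass. Neither arginine fermentation gene, arcA (arginine deiminase) or arcC (carbamate kinase), passed. The 3 histidine degradation genes fell, with a median of −0.154 beside −0.165 (SD 0.0505) for the 380 unnamed features. Within 2 SD of the latter lay 35 of the 74 named genes that changed, among them hutI, hutU, hutG, bat, mamA, pan1 and htr1.

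The difference passed for 1652 features, 301 higher and 1351 lower (1792 at an unadjusted p of 0.05), and for 993 with time points whitened for serial correlation. Centring gave 636 higher and 829 lower, quantile normalization 344 and 328, the loess 353 and 397, and the channel-2 arrays alone 149. After the loess pan1 was at 0.0190 and gatC (−0.141 as deposited) at 0.00875; neither passed there, nor did phoU, cbiT, cobN, bat, hutI, hutU, htr1 or mamA. With the sign turned 264 features passed, and none of the genes named for this shift; of those, sucC, sucD, hemA, eno, cbiT, bat, dpsA, htr1, htr7 and pan1 turned their direction.

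How expression went on changing in low oxygen was asked over the 13 time points from 362 to 747 minutes. In the tricarboxylic acid cycle sucC had a slope of −0.0633 ± 0.00659 and sucD of −0.0595 ± 0.00684 (SE, n = 13 time points) per doubling, and sucC went from 0.0748 at 362 minutes to −0.260 at 747 minutes. The slopes of dnaK, mdh and glyA were −0.0592 ± 0.00620, −0.0525 ± 0.00627 and −0.0444 ± 0.00731. The gene pan1 rose, with a slope of 0.0657 ± 0.00734, from −0.0510 at 362 minutes to 0.296 at 747 minutes; its slope was 0.00787 in the channel-1 arrays and 0.124 in the channel-2 arrays. Smaller rises were those of mamA (0.0308 ± 0.00686), mch (methenyl-tetrahydromethanopterin cyclohydrolase, 0.0230 ± 0.00588) and the DNA repair genes radB (0.0223 ± 0.00773) and mutL (0.0215 ± 0.00520). All 5 of these slopes were below 0 with the sign turned, and those of pan1 (−0.0579) and mamA (−0.0202) passed.

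Here 5 of 6 genes of the tricarboxylic acid cycle fell, and 6 when adjusted over the list alone (median −0.0368; camera, adjusted p = 7.04e-07; adjusted p = 0.0234 with an estimated correlation and 0.343 with the sign turned). The cobalamin genes cobN (−0.0291), cbiG (−0.0280) and cbiT (−0.0280) fell, 3 of 4 and 3 when adjusted over the list alone (camera, adjusted p = 0.00157; adjusted p = 0.0234 with an estimated correlation; 0.375 after the loess). Under flagella and chemotaxis cheA, cheY and cheB fell (cheB was 0.00231 after the loess) while the receptor genes htr1, htr6, htr7 and htr18 rose, so 4 of 11 rose and 3 fell, with a median of −0.000927, and 4 of the 7 genes of a chemoreceptor list chosen after the gene names were known rose. With centred arrays htr1, htr6 and htr7 did not pass, and htr6 did not relative to neighbouring spots. Of 3 rhodopsin genes hop (halorhodopsin, a light-driven chloride pump, 0.0205) and sop1 (sensory rhodopsin I, 0.0140) rose, a list chosen after the gene names were known, and sop1 did not pass with centred arrays (nor did radB). The slopes of these receptor and rhodopsin genes were below 0 with the sign turned, those of htr1 and htr7 past the threshold, and cbiT turned its direction. None of the rising genes named for this phase passed in the channel-1 arrays alone, where htr7 had a slope of 0.000100. After the loess cobN, cbiG, cbiT, cheA, cheY, cheB, glyA, mch, radB and sop1 did not pass. The trend passed for 872 features, 557 rising and 315 falling, and the 380 unnamed features had a median slope of 0.00917 (SD 0.0101). Within 2 SD of it lay 21 of the 58 named genes that changed. The rising genes mch, radB, mutL, hop, sop1, htr1, htr6, htr7 and htr18 were among them, and pan1 and mamA were not. Centring gave 238 rising and 442 falling, quantile normalization 315 and 368, the loess 351 and 319, and the channel-1 arrays alone 428. Without the time point at 367 minutes, whose channel-2 array is titled as high oxygen, 572 passed, and with the sign turned 511.

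Which genes differed between the phases of high and low oxygen was asked by setting the 8 time points of the first high-oxygen phase against the 9 of the low-oxygen phase. Values in the former were not steady as deposited, with a trend in 2051 features (98 with the sign turned). Whether the culture, the dye effect or a batch changed over that phase cannot be told. Lower in high oxygen were rpl12p (−0.380 ± 0.0787, SE; −0.189 ± 0.267, SD, n = 8, against 0.192 ± 0.149, n = 9) and rpmC, named for a protein of the large ribosomal subunit (−0.244). Also lower were secY, the channel through which proteins leave the cytoplasm (−0.203 ± 0.0293), and csg, the glycoprotein of the surface layer (−0.173 ± 0.0233). The translation initiation factor gene infB was higher, by 0.106 ± 0.0197 (limma, adjusted p = 0.000332). Among time points 45 minutes or more after each shift the difference was −0.141 for rpl12p, no longer past the threshold, and −0.162 for secY, −0.140 for csg and 0.151 for infB, each past it.

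Also higher in high oxygen were truA (tRNA pseudouridine synthase, 0.162 ± 0.0260), purB (0.158 ± 0.0407), gatC (0.144 ± 0.0443), hutI (0.143 ± 0.0335), deoC (deoxyribose-phosphate aldolase, 0.136 ± 0.0246), tmk (thymidylate kinase, 0.108 ± 0.0290) and cbiQ (cobalt uptake, 0.106 ± 0.0260). The 380 unnamed features were higher by a median of 0.144 (SD 0.0380), and 24 of the 55 named genes that changed, those 7 and infB among them, lay within 2 SD of it. Further lower genes were eno (−0.133 ± 0.0414), guaB (−0.120 ± 0.0295), the ferredoxin gene fer2 (−0.115 ± 0.0371) and hemA (−0.102 ± 0.0391). Of the tricarboxylic acid cycle citZ rose (0.0458) and icd fell (−0.0593), 1 of 6 each and 1 of 6 when adjusted over the list alone. The list's median was −0.0254 against 0.0435 for all features, so citZ rose about as much as features at large. In the haem list hemL rose (0.0553) and hemA fell; dpsA rose (0.0590) and msrA did not pass; of 2 chaperone genes dnaJ fell (−0.0508). The activator gene bat was at 0.0701, past the threshold, and at −0.00893 with quantile normalization, while nuoL fell (−0.0575). Of 12 aminoacyl-tRNA synthetase genes 3 rose, with glyS at 0.0985, of 6 histidine synthesis genes 3, with hisG at 0.0751 and hisI at 0.0732, and of 5 pyrimidine genes 2, with carA at 0.0981. The medians of these lists were 0.0170, 0.0421 and 0.0550, beside 0.0435 for all features. The 3 histidine degradation genes rose as deposited, and after the loess hutU was −0.00946 and hutG −0.0256. Of 11 flagella and chemotaxis genes the receptor gene htr4 rose (0.0641), of 3 rhodopsins sop2 fell (−0.0430), of 3 thiamine genes thiL rose and 2 fell, with thiC at −0.0623, and of 4 glutamate genes gdhA2 was at 0.0399, past the threshold, and at −0.0809 after the loess. Of 7 purine genes 2 rose and 1 fell, and of 3 DNA repair genes none passed in limma (mutL had the largest difference). The genes arcA and arcC, by which this organism ferments arginine without oxygen, did not pass, nor did phoU (0.0166; −0.0175 with centred arrays; −0.000896 to 0.0235 with 1 time point left out, the lowest without 180 minutes). Relative to neighbouring spots citZ, icd, hemL, hemA, dnaJ, hisI, nuoL, eno, sop2 and thiC did not pass, with centred arrays citZ, hemL, bat, thiL, hisI, htr4, gdhA2 and dpsA did not, and after the loess icd, carA, bat, thiL, gatC, hutG, hutU and tmk did not, with thiL at −0.0433. None of the 14 lists tested passed in camera (lowest adjusted p = 0.514), and the histidine degradation list was not among them.

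This difference passed for 1498 features, 1245 higher and 253 lower (1624 at an unadjusted p of 0.05). Centring gave 929 higher and 567 lower, quantile normalization 355 and 415, and the loess 555 and 518. Among time points 45 minutes or more after each shift 287 features passed, and 224 with oxygen state and elapsed minutes as a covariate. The latter set the first high-oxygen phase and the second shift to high oxygen against the low-oxygen phase and the time point before the first shift. With the sign turned 963 passed, and rpl12p, secY and csg were at 0.0339, 0.0476 and 0.0507. In that case secY, csg and icd passed as higher and hisI and cbiQ as lower, against their direction as deposited, and infB (−0.0134), rpmC (0.0453), eno (0.0190), fer2 (0.0340), hemA (0.0253), dpsA (−0.0318), bat, nuoL and htr4 turned without passing. As deposited but from 45 minutes on, hemA was at 0.0269, icd at 0.00812 and bat at −0.0120, none of them past the threshold. The channel-2 arrays alone gave 447.

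**Figure D2:**
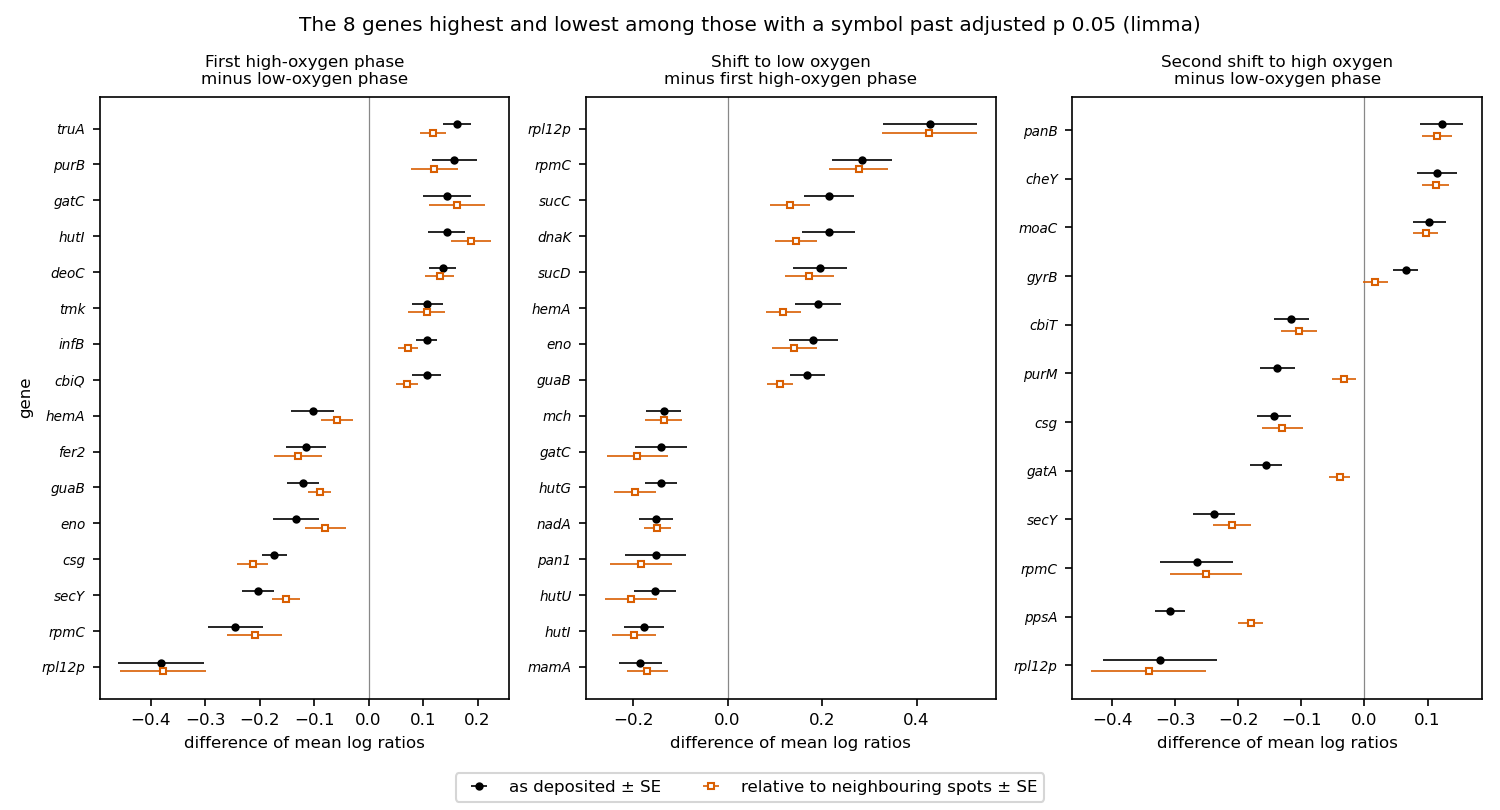
Differences (x axis, log-ratio units) of the named genes with the highest and lowest values in 3 comparisons; black points are values as deposited with SE, orange points the differences relative to neighbouring spots of the print block. The gene rpl12p was at −0.380, 0.429 and −0.324 as deposited.

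What changed in the first 30 minutes after oxygen returned was asked by setting the 5 time points of the second shift to high oxygen against the 9 of the low-oxygen phase. Again rpl12p was lower (−0.324 ± 0.0903, SE; −0.133 ± 0.0439, SD, n = 5, against 0.192 ± 0.149, n = 9), with rpmC (−0.266 ± 0.0574), secY (−0.239 ± 0.0336) and csg (−0.143 ± 0.0267); with the sign turned the 4 were at 0.0819 (past the threshold), 0.0552, 0.0366 and 0.0526, and with centred arrays rpl12p did not pass. By 747 minutes, before oxygen returned, rpl12p was already at −0.152 and secY at −0.0134. The value of secY was −0.163 in the channel-1 array and 0.136 in the channel-2 array, so its fall there rests on 1 array. The response regulator gene of chemotaxis, cheY, was higher by 0.115 ± 0.0317, with panB (0.122 ± 0.0346), moaC (molybdenum cofactor synthesis, 0.103 ± 0.0261) and gyrB (DNA gyrase, 0.0653 ± 0.0196); with the sign turned panB, moaC and gyrB were at −0.00102, −0.0123 and −0.0219, and relative to neighbouring spots gyrB did not pass. The gene ppsA, for phosphoenolpyruvate synthase, fell by 0.308 ± 0.0233 (−0.0975 ± 0.0571, n = 5, against 0.211 ± 0.0316, n = 9), as −0.584 in the channel-1 arrays and −0.0324 in the channel-2 arrays.

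Next to ppsA on the array, gatA (−0.156 ± 0.0252; −0.360 and 0.0474 in the 2 orientations) and the purine gene purM (−0.138 ± 0.0273) were lower too, and 46 unnamed features around these genes had a median of −0.114, 44 of them lower than the median of all features, −0.0227. Relative to neighbouring spots ppsA was at −0.181 and past the threshold, gatA at −0.0396 and purM at −0.0326, both not. The map of differences by position shows this area as a patch. Both arginine fermentation genes fell, arcA (−0.103 ± 0.0335) and arcC (−0.0710 ± 0.0190), 2 of 2 and 2 when adjusted over the list alone; relative to neighbouring spots arcA did not pass, and with centred arrays neither did. The cobalamin gene cbiT fell (−0.116 ± 0.0273), as did nuoL (−0.0790) and the triosephosphate isomerase gene tpiA (−0.0973); relative to neighbouring spots nuoL and tpiA did not pass, and with centred arrays cbiT and nuoL did not. Of these, cbiT was at 0.0445 with the sign turned, and arcA, arcC, nuoL and tpiA were above 0 as well, none past the threshold. Of 4 genes of glycolytic carbon metabolism, a list chosen after the gene names were known, 2 fell, ppsA and tpiA (camera, adjusted p = 0.00445; adjusted p = 0.0396 with an estimated correlation and 0.811 with the sign turned). In the channel-2 arrays alone 0 of 14 lists passed in camera, this one included. None of the 6 genes of the tricarboxylic acid cycle passed in limma, and sucC differed by −0.00817 (adjusted p = 0.939). The mean of the low-oxygen phase takes in the fall of sucC through it, so a rise from the last level need not show.

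**Figure D3:**
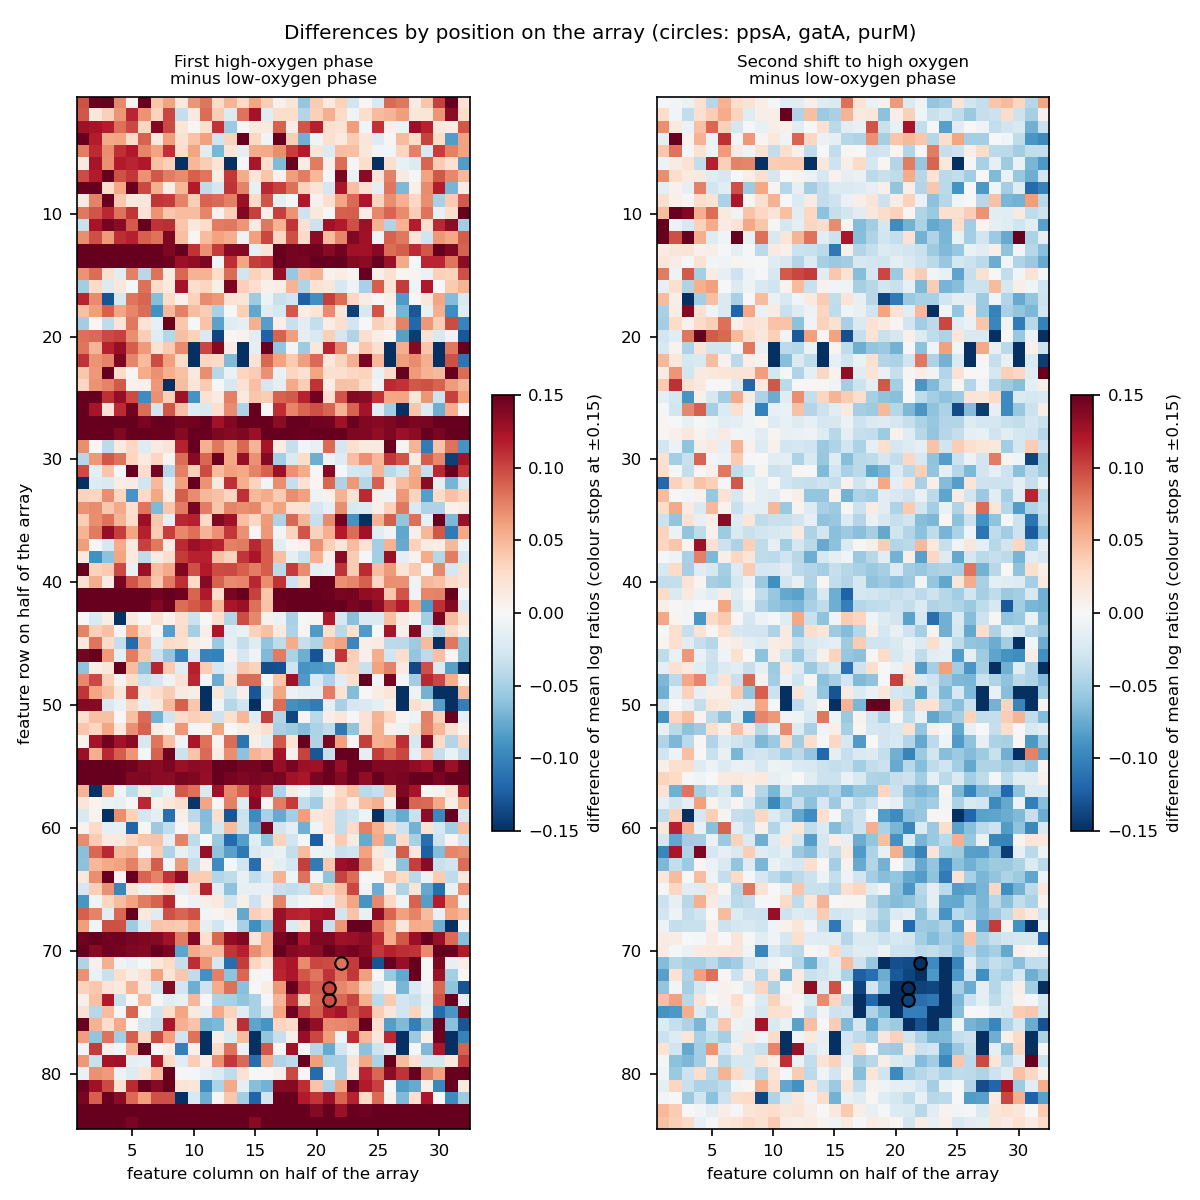
Differences of all features (colour, log-ratio units) at their place on the array (x axis, column; y axis, line of features) for high against low oxygen and for the second shift to high oxygen against low oxygen; circles mark ppsA, gatA and purM. Print blocks held 8.56% and 15.1% of the variance.

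The difference passed for 281 features, 86 higher and 195 lower (626 at an unadjusted p of 0.05), for 86, 26 higher and 60 lower, with time points whitened for serial correlation, and for 463 with only the 2 groups fitted. Centring gave 148 higher and 103 lower, quantile normalization 293 and 247, the loess 197 and 176, and the turned sign 175 in all. Leaving out the time point at 755, 760 or 770 minutes gave 169, 187 and 175, and 56 features passed without 755 and 770 minutes, the time points in doubt for a wide channel-2 array and for missing values.

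Whether the same minutes after each shift to high oxygen gave the same levels was asked over 5 pairs of time points, at 0, 5, 10, 20 and 30 minutes. After the second shift rpl12p was higher by 0.254 ± 0.0252 (SE; −0.133 ± 0.0439, SD, n = 5, against −0.386 ± 0.0453, n = 5), glyA by 0.212 ± 0.0274, dnaK by 0.185 ± 0.0264 and hemA by 0.185 ± 0.0239. The chemotaxis genes cheY (0.152 ± 0.0255) and cheA, the histidine kinase (0.132 ± 0.0293), were higher too, with guaB (0.131 ± 0.0253) and sdhC (0.125 ± 0.0219). Lowest were ppsA (−0.417 ± 0.0258; −0.891 and 0.0562 in the 2 orientations), hutI (−0.302 ± 0.0217), gatC (−0.298 ± 0.0374), purM (−0.298 ± 0.0223), gatA (−0.297 ± 0.0235), purB (−0.293 ± 0.0270), mamA (−0.260 ± 0.0245) and hutU (−0.256 ± 0.0257), with 4 time points after the second shift for gatC, purB and hutU. The 46 unnamed features around ppsA, gatA and purM had a median of −0.285, and the 380 unnamed features of −0.262 (SD 0.0523). Within 2 SD of the latter lay 20 of the 86 named genes that changed, hutI, gatC, purM, gatA, purB, mamA and hutU among them. In the 380 unnamed features and in hutI levels already differed before oxygen was raised. The 380 unnamed features had a median of 0.357 at 1 minute before the first shift and 0.0840 at 747 minutes. At these time points hutI was at 0.347 and 0.0974. The comparison is of levels and by itself does not show another response to the second shift. Earlier levels of the other genes were not set beside it here. The mean of ppsA fell between 747 and 750 minutes, so an earlier level need not account for its difference.

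Between the shifts 4 of 6 genes of the tricarboxylic acid cycle were higher at the second, sucC (0.118), mdh (0.117) and sucD (0.0880) besides sdhC, and 4 when adjusted over the list alone (camera, adjusted p = 0.000922; adjusted p = 0.209 with an estimated correlation, 0.195 with quantile normalization and 0.255 after the loess). Relative to neighbouring spots sucC differed by 0.00282 and mdh did not pass; with the sign turned sucC, sucD, mdh and sdhC did not pass. The flagella and chemotaxis list passed as higher than other genes (camera, adjusted p = 0.0387), but not with an estimated correlation (0.305), with centred arrays (0.0544), relative to neighbouring spots (0.316), with quantile normalization (0.195), after the loess (0.878) or with the sign turned (0.157), with cheA, cheY and cheB higher and the receptor genes htr18, htr7 and htr2 lower, 6 of 11 when adjusted over the list alone. Its median was −0.00321 and its mean 0.0142 against −0.0984 for all features, and with centred arrays htr7 and htr2 were at 0.0238 and 0.0251 and htr18 did not pass; in the channel-2 arrays alone cheA, cheY, cheB and these 3 receptor genes did not pass. Both arginine fermentation genes were lower, arcA (−0.144 ± 0.0287) and arcC (−0.0709 ± 0.0192), and with centred arrays neither passed and arcC was at 0.0260. The gene arcA passed as higher (0.131) with the sign turned, and cheB, htr18, sucC, sucD and hemA turned their direction without passing.

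This difference passed for 1961 features, 291 higher and 1670 lower (2020 at an unadjusted p of 0.05). With centred arrays 984 were higher and 1016 lower, with quantile normalization 460 and 459, after the loess 536 and 551, and with the sign turned 413 passed. The channel-2 arrays alone gave 1153. The loess put purM at 0.0128 and gatA at 0.0164.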

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

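All tests in this part were chosen after the results had been seen. In 4 genes the time point at 750 minutes, the moment of the second shift to high oxygen, stood apart from the 4 later ones: cheA was at −0.258 (others −0.0474 to 0.0143), cheY at −0.178 (−0.0153 to 0.0263), glyA at −0.307 (−0.0881 to −0.0269) and mdh at −0.170 (−0.0337 to −0.00504). In the low-oxygen phase secY was at −0.0134 at 747 minutes (others 0.102 to 0.190), −0.163 in the channel-1 array and 0.136 in the channel-2 array. In the first high-oxygen phase hemL was at −0.0565 at 180 minutes (others 0.0572 to 0.113), 0.0861 in the channel-1 array and −0.199 in the channel-2 array. Chance gives about 1 in 20 groups with such a value, 11.2 of the 224 groups tested over 56 genes, and 6 were found. The genes ppsA (−0.417; limma, adjusted p = 2.47e-07), purM (−0.298; adjusted p = 2.47e-07) and gatA (−0.297; adjusted p = 2.66e-07) differed between the second and the first shift to high oxygen, and these differences were tested over 5 pairs of time points.

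The genes ppsA, gatA and purM, which are close to each other on the array, were lower in the second shift to high oxygen than in the low-oxygen phase. Against the median of 46 unnamed features around them, −0.114, the difference of purM lay −0.347 and that of gatA −0.607 SDs away, as position on the array would give, and position may account for both. That of ppsA lay −2.76 SDs away with 1 of the 46 at or below it, so position as its whole cause stays open. Lower RNA with the return of oxygen stays open too: in the channel-2 arrays ppsA differed by −0.0324 (limma, adjusted p = 0.485) and gatA by 0.0474 (adjusted p = 0.220). For purM no biological explanation was tested.

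The genes sucC and sucD rose over the first high-oxygen phase. Position on the array as the whole cause is argued against by slopes relative to neighbouring spots. These were 0.0385 for sucC (limma, adjusted p = 3.69e-05) and 0.0551 for sucD (adjusted p = 9.03e-07). After the loess the slopes were 0.0361 (limma, adjusted p = 0.000730) and 0.0368 (adjusted p = 0.000169). The loess works on the mean of both orientations and does not model the scale of each array. Scaling between arrays therefore stays open. A drift of the dye effect stays open: the slopes had 1 sign in both orientations, 0.0618 (adjusted p = 1.64e-05) for sucC and 0.0588 (adjusted p = 4.72e-06) for sucD in the one with the higher p, but the sign was kept because orientations move alike, and with it turned sucC was at 0.00410 and sucD at −0.00238. A batch that follows time, higher RNA with time in high oxygen and flowing medium are not parted by the design and stay open as well. Whether the return of oxygen by itself raises them cannot be told from the second shift. There sucC differed by −0.00817 (limma, adjusted p = 0.939) from the mean of the low-oxygen phase. It had fallen through that phase, so a rise from its last level need not show.

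The genes hutI, hutU and hutG fell over the first high-oxygen phase. Their slopes lay 0.354, −0.481 and 0.874 SDs from the median of the 380 unnamed features at the end of the print blocks, −0.0548, so what moves those spots may be the whole cause. Lower RNA with time in high oxygen stays open: after the loess the slope was −0.0140 for hutU (limma, adjusted p = 0.0203), which that explanation needs, and −0.00184 for hutI (adjusted p = 0.747) and 0.00589 for hutG (adjusted p = 0.335), which do not decide.

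For 4 comparisons the time points were split otherwise 100 times, the real split included, and in each comparison 1 split, the real one, gave as many features. For high against low oxygen the real split gave 1498 and the highest other 0, for the shift to low oxygen 1652 and 1510, for the second shift to high oxygen against low oxygen 281 and 15, and for the second against the first shift 1961 and 956. Of the 12 splits that parted all pairs of minutes since the shift, 1, the real one, gave as many, and the highest other gave 89. Time points of 1 culture that follow each other are alike, so these splits do not show what chance gives, and they settle nothing about it.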

How the results depend on the processing

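Zeros kept as values, the loess, values relative to neighbouring spots, the turned sign, leaving out 755 and 770 minutes and leaving out the 380 unnamed features were chosen after seeing the data, and the other alternatives before it. Over all other settings 1476 results kept their direction and threshold, 323 weakened, 3 strengthened and 78 turned their direction; with 1 time point left out the numbers were 1269, 78, 1 and 1. Counts stayed within 1.5 times in 87 cases and moved beyond it in 33, and with 1 time point left out in 71 and 4. The cause of these changes was not tested unless a test is named. Differences between time points have a floor, with 1 culture and no scanner intensities. In simulated data with independent time points 20.5% of changes of 0.05 were recovered for high against low oxygen. The shares were 11.3% for the shift to low oxygen, 6.85% for the second shift against low oxygen and 0% between the shifts. Zeros kept as values, the median over spots, both arrays with a random block, no block of minutes, ranks of time points and the whitened list test turned no direction.

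With an adjusted p of 0.01 the counts were 1068 for the shift to low oxygen, 136 for the second shift against low oxygen and 406 for the trend in low oxygen. Whitened time points gave 993 and 86 for these shifts, and only the 2 groups compared 463 for the second. Without the features whose orientations disagree most 931 passed for high against low oxygen and 1097 for the shift to low oxygen. Without the 380 unnamed features 1105 (866 higher) passed for high against low oxygen, 1273 (294 higher) for the shift to low oxygen, 314 (99 higher) for the second shift against low oxygen, 1587 between the shifts, and 1662 and 879 for the trends; sop2 and the flagella list no longer passed. The second shift against low oxygen had 169 to 331 with 1 time point left out (169 without 755, 187 without 760 and 175 without 770 minutes) and 56 without 755 and 770 minutes. The trend in low oxygen had 572 to 938, lowest without 367 minutes. Of 8 lists past the threshold in camera, 4 passed with an estimated correlation and 3 after the loess. Relative to neighbouring spots 3 lists passed for the second shift against low oxygen, where 1 did as deposited. Those added were proteasome and proteases and flagella and chemotaxis (camera, adjusted p = 0.00311 each). With centred arrays neither of these passed (camera, adjusted p = 0.454 and 0.241). With the sign turned 2 lists passed, neither of them among the 8. With the sign as deposited 38 passed in fry, which tests a list against no change and not against other genes.

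With quantile normalization the counts were 770 for high against low oxygen, 672 for the shift to low oxygen, 540 for the second shift against low oxygen, 919 between the shifts and 914 for the trend in high oxygen, and after the loess 750 for the shift to low oxygen, 1087 between the shifts and 1062 for the trend in high oxygen. High against low oxygen turned with quantile normalization in bat (−0.00893), mutL (−0.00735), gdhA2 (−0.0390) and ppsA (−0.00504), after the loess in tmk (−0.00154), gdhA2 (−0.0809) and ppsA (−0.0311), and with centring in phoU (−0.0175), which ran from −0.000896 (without 180 minutes) to 0.0235 with 1 time point left out. The loess turned pan1 (0.0190) and gatC (0.00875) in the shift to low oxygen and purM (0.0128) and gatA (0.0164) between the shifts.

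Channel-1 arrays alone gave 428 for the trend in low oxygen and turned arcA (−0.00646) and hisI (−0.00981) in high against low oxygen. Channel-2 arrays alone gave 447 for high against low oxygen, 149 for the shift to low oxygen and 1153 between the shifts; they turned ppsA in high against low oxygen (−0.0685) and between the shifts (0.0562), and gatA in the second shift against low oxygen (0.0474) and between the shifts (0.0555).

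Time points from 45 minutes on gave 287 for high against low oxygen and turned hemA (0.0269), bat (−0.0120), icd (0.00812) and mutL (−0.0479); oxygen state with elapsed minutes gave 224 and turned arcA (−0.0243), bat (−0.000256), mutL (−0.00529), gdhA2 (−0.0104) and ppsA (−0.115). Relative to neighbouring spots arcA (−0.00350) and phoU (−0.0308) turned, and with centring too arcA (−0.0474), citZ (−0.0135), hemL (−0.00386), phoU (−0.0747), hisI (−0.0192) and ppsA (−0.00971), with gatA between the shifts (0.00966).

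With the sign turned the counts were 963 for high against low oxygen, 264 for the shift to low oxygen, 175 for the second shift against low oxygen, 413 between the shifts, and 98 and 511 for the trends. High against low oxygen turned in infB (−0.0134), cbiQ (−0.0794), rpl12p (0.0339), rpmC (0.0453), secY (0.0476), csg (0.0507), eno (0.0190), fer2 (0.0340), hemA (0.0253), arcA (−0.0489), bat (−0.0478), nuoL (0.00223), icd (0.0370), dpsA (−0.0318), panB (−0.0429), htr4 (−0.00685), phoU (−0.0135) and hisI (−0.0830). The shift to low oxygen turned in rpmC (−0.0658), sucC (−0.00464), sucD (−0.00917), hemA (−0.00406), eno (−0.0287) and pan1 (0.0814), and the second shift against low oxygen in panB (−0.00102), moaC (−0.0123), gyrB (−0.0219), rpl12p (0.0819), rpmC (0.0552), secY (0.0366), csg (0.0526) and cbiT (0.0445). Between the shifts hemA turned (−0.00313). The trend in high oxygen turned in sucD (−0.00238), pan1 (0.0493), mamA (0.0139) and the tricarboxylic acid cycle (camera, adjusted p = 0.831), and the trend in low oxygen in pan1 (−0.0579) and mamA (−0.0202), both past the threshold, and in mch (−0.00197), radB (−0.00170) and mutL (−0.00604).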

Other observations

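All genes in this part were chosen after their values had been seen. The genes phoU, folP and purF, picked by hand and not tested as a group, had higher values within minutes of the loss of oxygen than in most of the first high-oxygen phase. The purine list, to which purF belongs, did not pass for this shift (camera over 6 genes, adjusted p = 0.0529). It passed relative to neighbouring spots (camera, adjusted p = 0.0489) but not with an estimated correlation (0.220). Of its 7 genes 3 rose and 2 fell. The phosphate regulator gene phoU was at −0.268 at 360 minutes, −0.142 at 362 minutes, −0.313 at 387 minutes and −0.328 at 747 minutes; against the first high-oxygen phase it rose by 0.147 ± 0.0254 (limma, adjusted p = 0.00114; 4 against 8 time points), and it then fell with a slope of −0.0414 (adjusted p = 0.000338). The gene folP, named for dihydropteroate synthase of folate synthesis, was at 0.0326 at 360 minutes, 0.182 at 362 minutes, 0.117 at 387 minutes and −0.0208 at 417 minutes, and its highest value, 0.234, came 1 minute before the first shift. The gene purF, for the enzyme that starts purine synthesis, was already at 0.0976 at 360 minutes, then at 0.145 at 367 minutes and −0.0322 at 382 minutes. After the loess the shift to low oxygen differed from the first high-oxygen phase by 0.0119 in phoU (adjusted p = 0.691), 0.157 in folP (adjusted p = 0.000774) and 0.0769 in purF (adjusted p = 0.0733).

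The time point 1 minute before the first shift is in none of the contrasts or trends, and counts as low oxygen only in the setting with elapsed minutes as a covariate. There rpl12p was at −0.421, sucC at −0.273, dnaK at −0.327 and pan1 at 0.320, beside −0.364 for rpl12p and −0.259 for sucC at the shift itself. Each is a single time point, and the earlier history of the culture is not given in the sources used here.

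Comparisons that share a group are correlated by it. For high oxygen and for the second shift, both against low oxygen, the differences correlated at r = 0.272 across 2688 features (features are not independent replicates). The r was 0.409 in data simulated without change, with independent time points, and 0.225 with the shared time points divided between them. The covariance was 0.00112, beside 0.000343 simulated, so covariance and r differ in which is the larger. For high oxygen against low oxygen and the shift to low oxygen against high oxygen r was −0.830, beside −0.421 simulated, and the covariance −0.00634, beside −0.000390.

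The orientations correlated across features at 0.837 and 0.552 for the trends in high and low oxygen. The r was 0.573 for high against low oxygen, 0.760 for the shift to low oxygen, 0.277 for the second shift against low oxygen and 0.683 between the shifts. The sign was kept because the orientations move alike over time, so these values are no separate evidence for it.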
